A study of Mus musculus with 5 samples.

How the data were processed

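The 3' mRNA libraries (a QuantSeq kit for Ion Torrent) had been made from RNA of iNKT cells of mouse liver, sorted as cells binding both a CD1d tetramer loaded with the lipid PBS57 and an antibody to the T cell receptor beta chain, after a Percoll step and lysis of red cells in water. The deposited values are raw whole-number counts per Ensembl gene ID, without normalization, 1 table per library, for 2 healthy and 3 HCC libraries described as from separate mice. The submitters' notes name bcl2fastq, HISAT2, Bowtie2, DESeq, DESeq2, edgeR and limma without roles or versions, and the genome build mm10. The counting program, its annotation and its strand setting were not given in the sources used here. All tables hold the same 55364 gene IDs. Symbols and positions were taken by gene ID from GENCODE M21, which gave a symbol to 55104 of them, and the other 260 held 0.763 to 1.08% of the counts.

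Several features of the counts limit what a row stands for. Rows of pseudogenes held 31.7 to 38.5% of the counts and rows of snoRNA genes 2.9 to 3.6%. Some genes that overlap on the genome had counts close to each other, such as Snora31 and Tpt1 with 13741 and 14424 in healthy 1 and 9358 and 11541 in healthy 2, so a read may have been counted for more than 1 gene. For each named gene, the share of 31-base words in the last 300 bases of its annotated transcripts that also occur in other genes was computed and is given in the report for globin, Mup and NK receptor genes, Acp1, Ttr, Apoa1 and Alb. It was also high in Bcl2a1b (88.5%), Hspa8 (81.2%), the Atp5o row (56.3%), Etfb (45.6%), AC121783.1 (39.6%), the Aldoa row (38.4%), Rps18 (38.0%) and Lyz2 (34.1%), and 26.4% (Ldha) or less in the other genes named by rule.

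Total counts were 1718452 to 2224356 per library. A count of 0 was read as allowing 3 counts in each library, which corresponds to 1.58 to 1.64 CPM. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its defaults by group (8468 of them), scaled with TMM, whose factors were 0.8299 and 1.036 for healthy 1 and 2 and 1.038, 1.12 and 0.9996 for HCC 1, 2 and 3, and tested with the quasi-likelihood F test of HCC against healthy. Adjusted p values are those of Benjamini and Hochberg with a threshold of 0.05. The common dispersion was 0.289. SE values of log2 fold changes come from the same edgeR fit, and no SE is given where a group had only counts of 0.

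Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01 between genes, adjusted over the lists with at least 5 tested members (28 of 34), and again with a correlation estimated for each list and with fry. With the estimated correlation 0 lists passed at the adjusted threshold and 1, the erythroid markers, was at an unadjusted p under 0.05. fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes, gave 0 lists at the adjusted threshold and 2 at an unadjusted p under 0.05. The lists cover T cell receptor and CD3 genes, iNKT identity, the NKT1, NKT2 and NKT17 subsets, regulatory and IL-10 associated genes, cytotoxic effectors, inhibitory receptors and exhaustion, cytokines and chemokines, immediate-early and NF-kB response, heat shock and dissociation stress, unfolded protein and integrated stress response, proliferation, type I interferon response, glycolysis, oxidative phosphorylation, fatty acid uptake and oxidation, cholesterol and lipid synthesis, residency and trafficking, TGF-beta signalling, apoptosis, p53 targets, ribosomal proteins, mitochondrially encoded genes, and markers of naive T cells, NK cells, B and plasma cells, macrophages and Kupffer cells, neutrophils, dendritic cells, hepatocytes, liver endothelium, stellate cells and fibroblasts, and the erythroid lineage. Each list's members were also adjusted over the list alone.

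The groups, the tests, the lists, the rule for named genes and most alternatives were chosen before the data were examined. Named genes were, first, the 12 with the highest and the 12 with the lowest fold change among called genes with a mean of at least 10 CPM and all HCC libraries on 1 side of both healthy libraries, leaving out Gm, Rik and -ps names. Since no gene was called, these places were filled by smallest unadjusted p. Second came up to 3 called members of each list or, with none called, its 2 members with the highest mean level, and last Cd3e, Trac, Zbtb16, Tbx21, Il2rb and Klrb1c. AC121783.1 is a pseudogene whose name the rule lets through. The values of 2 genes that the rule names are not reported here.

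Alternatives planned in advance were DESeq2 size factors, library totals only for the gene test, no filter on low counts, a filter of 10 CPM in 2 libraries, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, HCC 2 and 3 summed to 1 library because the names of their tables share a number and they may come from 1 mouse, although the titles and the design text count 3, markers of other cell types removed, and each library left out in turn. Protein-coding genes only, limma-voom with sample quality weights, and library totals only for the lists were added after the data had been seen. The pipeline was tested on simulated data: 10 simulations of 8468 genes with the fitted spread and no library set apart from the others. In these, 42 of 82680 unchanged genes were called. With genes drawn independently, camera called 19 of 20 lists raised 2-fold and 0 of 230 unchanged lists. This does not measure false calls for lists whose genes vary together. Against the preset 0.01, the estimated correlation was 0.659 in the hepatocyte, 0.626 in the erythroid, 0.0762 in the interferon and 0.0131 in the ribosomal list. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No column of the tables was left out.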

Results

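The transcriptomes compared here are those of invariant natural killer T (iNKT) cells, lymphocytes that recognise lipids presented by CD1d, sorted from mouse liver. Male wild-type C57BL/6 mice either received PBS (healthy) or a single dose of 25 mg/kg diethylnitrosamine (DEN), a hepatic carcinogen, at 15 days of age, and developed hepatocellular carcinoma (HCC). Livers were taken between 38 and 42 weeks of age. There were 2 healthy libraries and 3 HCC libraries of 3' mRNA sequencing, described as from separate mice. Total counts were 2224356 in healthy 1, 1821863 in healthy 2, 1837653 in HCC 1, 1718452 in HCC 2 and 1883979 in HCC 3. A count was present for 10861 genes in healthy 1, the fewest of the 5 libraries, and for 13229, 13059, 11822 and 12054 genes in healthy 2, HCC 1, HCC 2 and HCC 3. Levels are CPM, counts relative to the library total after TMM scaling, and a count of 0 allows a level of up to 1.58 to 1.64 CPM. Group values are means ± SD with n = 2 healthy and n = 3 HCC libraries, and fold changes are HCC over healthy. These limits cover counting error only, since the counts are of reads and not of distinct molecules.

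The comparison asked how gene expression of hepatic iNKT cells differs between tumour-bearing and healthy livers. The genes with the smallest p values and higher levels in all 3 HCC libraries were mostly transcripts of red cells and hepatocytes. Hbb-bs, an adult beta globin, was at 379.7 ± 122 CPM in healthy and 2200 ± 1031 CPM in HCC libraries (log2 fold change 2.53, SE 0.50). Hba-a2, an alpha globin, was at 1382 ± 419 and 5346 ± 2176 CPM (1.95, SE 0.48). Among genes at lower levels in all 3 HCC libraries, Rbm3, a cold-inducible RNA-binding protein, was at 471 ± 172 CPM in healthy and 174 ± 62.9 CPM in HCC libraries (-1.44, SE 0.43). No single gene passed the test. Of 8468 genes tested with edgeR, 0 were higher and 0 lower at an adjusted p under 0.05, with a smallest adjusted p of 0.9998. At an unadjusted p under 0.05 edgeR gave 307 genes, 182 higher and 125 lower, where 423 would be reached by chance.

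DESeq2 called 9 genes higher and 0 lower, with 432 at an unadjusted p under 0.05. These 9, singled out after their values were seen, were Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2 and the major urinary protein genes Mup1, Mup8, Mup10, Mup13 and Mup22, which are expressed by hepatocytes. limma-voom called 0 higher and 0 lower, with 208 at an unadjusted p under 0.05, and with sample quality weights also 0 and 0, with 117. All 3 HCC libraries lay above both healthy libraries for 895 genes and below both for 715, together 19% of the genes tested, where chance gives 20%. Without healthy 1 edgeR called 0 genes in either direction, with 368 at an unadjusted p under 0.05. Leaving out healthy 2 gave 102 higher and 94 lower genes, in a fit that assumes the lone healthy 1 library to vary like the HCC libraries.

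Healthy 1 stood apart from the other libraries. Its Pearson r with them, across genes of log2 levels, was 0.763 to 0.815, whereas the other 4 libraries correlated with each other at 0.850 to 0.904 (genes are not independent replicates). The first principal component held 47.7% of the variance and placed healthy 1 at -98.1 and the others between 13.4 and 38.4. The names of the tables of HCC 2 and HCC 3 share a number, which leaves open whether both come from 1 mouse. These libraries had an r of 0.85 and were no closer to each other than the other pairs that leave out healthy 1. The common biological coefficient of variation was 53.8%. On simulated counts of the same size and spread, edgeR recovered 1%, 16.8%, 53.4% and 67.6% of genes changed 2-, 4-, 8- and 16-fold. Changes under 4-fold in single genes were thus rarely detectable. Every simulated library varied around the same means, apart from the changed genes, and none stood apart as healthy 1 did. Recovery of larger changes in the real data may therefore be lower. Mup10, at 22.4-fold between group means, had an adjusted p of 0.9998 in edgeR.

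The named genes at higher levels in all 3 HCC libraries fell into 3 kinds. None passed in edgeR with all libraries, the filter on low counts and no replicate block. Globins were 4 of the 12: besides Hbb-bs (ENSMUSG00000052305, chromosome 7, 103826534 to 103828096, mm10) and Hba-a2 (ENSMUSG00000069917, chromosome 11, 32296489 to 32297298) they were Hbb-bt, at 104 ± 54.6 and 556 ± 213 CPM, and Hba-a1, at 1297 ± 407 and 4565 ± 1801 CPM. Hepatocyte secretory genes were 5 of the 12. Ttr, which encodes the thyroxine carrier transthyretin (ENSMUSG00000061808, chromosome 18, 20665280 to 20674321), was at 1.62 ± 0.0264 and 26.7 ± 19.2 CPM. Apoa1, the main apolipoprotein of high-density lipoprotein, was at 1.09 ± 0.783 and 16.3 ± 9.46 CPM, with a log2 fold change of 3.83 (SE 1.05) that was 4.76 without healthy 1. Mup10, Mup11 and Mup22 had log2 fold changes of 4.45 (SE 1.13), 5.22 (SE 1.34) and 4.30 (SE 1.16). Mup10 and Mup22 were at 163 and 152 CPM in HCC 3 against 12.7 and 10.6 CPM in HCC 1, and the log2 fold changes of Mup10, Mup11 and Mup22 were 3.03, 4.40 and 2.74 without HCC 3. Without healthy 1 that of Mup11 was 4.30. Without healthy 2 those of Mup10 and Mup22 were 5.45 and 5.30, and none is given for Mup11, which had 0 counts in healthy 1. With no filter on low counts the 4 globins, Ttr, Mup10, Mup11 and Mup22 passed in edgeR (adjusted p from 2.51e-07 to 0.011), and Hbb-bs and Hbb-bt also passed with the replicate number as a block (0.0394) and without healthy 2 (0.0287 and 0.0224, with the log2 fold change of Hbb-bt at 3.14 against 2.42 with all libraries). Of the 31-base words at their 3' ends, 100% in Mup10 and Mup22, 73.6% in Mup11, 89.9% in Hba-a1, 85.0% in Hba-a2, 69.1% in Hbb-bs and 40.7% in Hbb-bt occur in other genes too, so these rows are not separate measurements. No word of Ttr, Apoa1 or Alb was shared.

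The others included genes of general cell functions. Polr2a, which encodes the largest subunit of RNA polymerase II (ENSMUSG00000005198, chromosome 11, 69733997 to 69758637), was at 23.5 ± 4.59 CPM in healthy and 80.2 ± 7.41 CPM in HCC libraries (log2 fold change 1.77, SE 0.42). Acp1, a low-molecular-weight phosphatase, was at 2.71 ± 0.0439 and 21.7 ± 4.71 CPM (2.97, SE 0.72), and 76.5% of its 3' words are also found elsewhere, mainly in the overlapping Alkal2.

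Among the 12 named genes at lower levels in all 3 HCC libraries, none of which passed in edgeR with all libraries, were single genes of respiration, sterol synthesis and signalling. The lists of oxidative phosphorylation and of cholesterol and lipid synthesis did not pass camera (adjusted p = 0.889 and 0.68). Ndufs6, a complex I subunit, was at 440 ± 223 and 199 ± 39.7 CPM (log2 fold change -1.15, SE 0.41), and the row of Atp5o, an ATP synthase subunit (ENSMUSG00000022956), was at 350 ± 20.2 and 183 ± 25.9 CPM (-0.94, SE 0.34). Msmo1, a sterol oxidase of cholesterol synthesis (ENSMUSG00000031604, chromosome 8, 64718139 to 64733792), was at 85.9 ± 12.5 and 35.4 ± 9.62 CPM (-1.28, SE 0.41). Map2k4, a kinase upstream of JNK, was at 21.2 ± 7.23 and 3.02 ± 2.71 CPM (-2.78, SE 0.92). Mtfr1l was at 104 ± 13.6 and 44.7 ± 5.21 CPM, Dnajc15 at 112 ± 45.1 and 46.0 ± 14.7 CPM, and Snrpd2, a core protein of spliceosomal particles, at 111 ± 38.5 and 53.2 ± 4.72 CPM. The histone demethylase Kdm2a and the kinase Riok3 had log2 fold changes of -1.73 (SE 0.60) and -1.66 (SE 0.58). AC121783.1, a processed pseudogene, was at 39.1 ± 12.9 and 12.2 ± 2.21 CPM. Healthy 1 held the highest level of all 12 of these genes. Without it the log2 fold changes of Kdm2a, Riok3 and Ndufs6 were -0.75, -0.91 and -0.51, while without healthy 2 Ndufs6 passed (-1.53, adjusted p = 0.0442 in edgeR) and without HCC 3 Map2k4 was at -3.67.

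Among the 28 tested lists, hepatocyte and erythroid markers had the largest median differences. All 17 tested hepatocyte markers had higher fitted levels in HCC libraries, with a median log2 fold change of 3.20 (2.97 with genes at 0 in a group set at their bound of 3 counts per library). Their summed level was 78.8 and 78.1 CPM in the healthy libraries and 120, 420 and 1053 CPM in HCC 1, 2 and 3. Alb, which encodes albumin, was at 4.38 and 17.7 CPM in healthy 1 and 2 and at 6.88, 53.02 and 201 CPM in HCC 1, 2 and 3 (7.90-fold between group means). Serpina3k, a hepatocyte serpin, was at 7.56 ± 2.17 and 58.5 ± 67.5 CPM. The log2 fold changes of Alb and Serpina3k were 2.97 and 2.94 with all libraries and 1.44 and 1.42 without HCC 3 (Alb 2.28 without healthy 1 and 4.34 without healthy 2), and both passed in edgeR only with no filter on low counts (adjusted p = 0.000226 and 0.00182). All 5 tested erythroid markers were higher in each HCC library than in both healthy libraries, with a median log2 fold change of 2.42 and summed levels of 3622 and 2717 CPM against 7188, 15430 and 15540 CPM. Both lists rose in camera with a preset correlation (hepatocyte adjusted p = 3.72e-16, erythroid adjusted p = 9.27e-14), whereas both had adjusted p = 0.646 with an estimated correlation. Of the hepatocyte members 11 passed adjusted over the list alone and 0 over all genes, and of the erythroid members 5 and 0. HCC 1, with 120 CPM of hepatocyte markers, lay close to the healthy libraries, and the erythroid count of 5 includes the globin pairs with shared sequence. The other tested erythroid member, Alas2, was at 0 and 12.8 CPM in healthy 1 and 2 and at 13.2, 69.8 and 56.9 CPM in HCC 1, 2 and 3. For Alas2, HCC 1 thus barely lay above healthy 2.

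**Figure D1:**
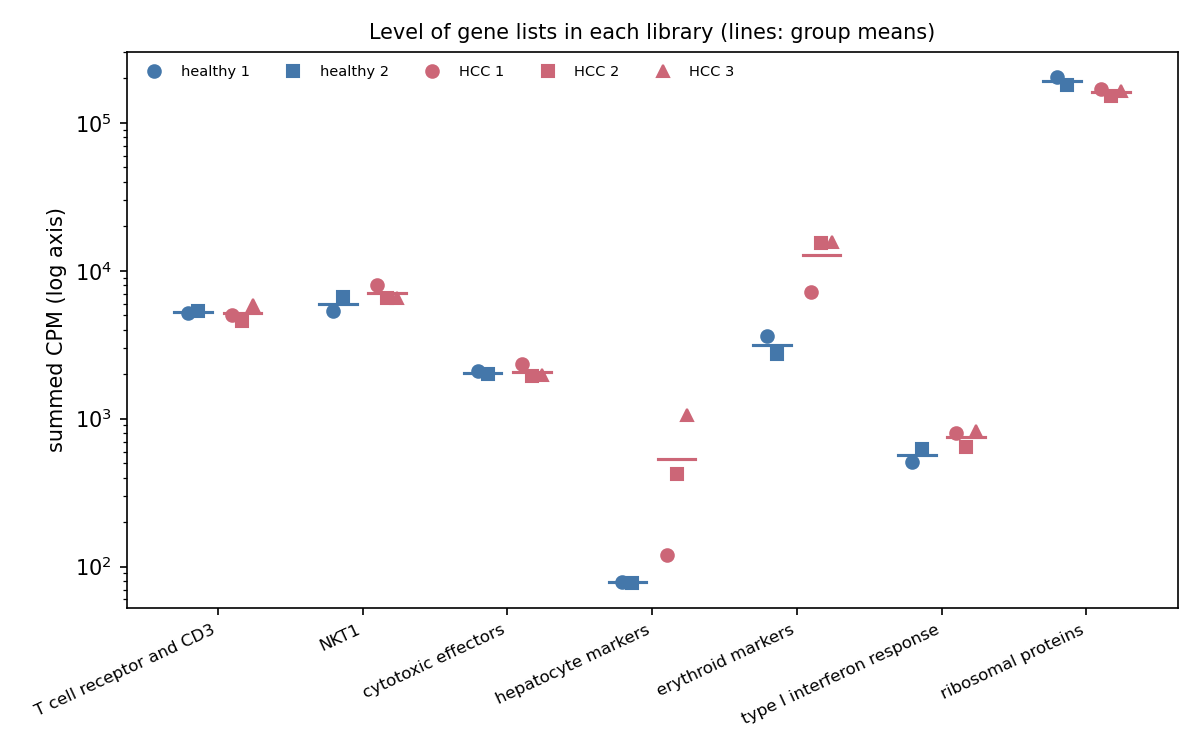
Summed level of 7 gene lists in each of the 5 libraries, in CPM on a log axis; points are libraries and lines are group means. Hepatocyte markers span 78.1 to 1053 CPM and erythroid markers 2717 to 15540 CPM, while the T cell receptor and CD3 list stays between 4550 and 5870 CPM.

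Interferon-stimulated genes were somewhat higher in HCC libraries as a list. Of 16 tested members of the type I interferon response list, 14 had higher fitted levels, with a median log2 fold change of 0.46, and 5 were higher in every HCC library than in both healthy libraries. Ifi47, an interferon-inducible GTPase, was at 242 ± 66.1 and 314 ± 52.1 CPM, and Ifi27l2a at 88.6 ± 16.2 and 112 ± 27.1 CPM. Summed levels were 509 and 622 CPM in healthy 1 and 2 and 798, 643 and 824 CPM in HCC 1, 2 and 3. The list rose in camera with a preset correlation (adjusted p = 0.00803) but had adjusted p = 0.646 with an estimated correlation, and 0 members passed adjusted over the list alone or over all genes. The call was also lost without healthy 1 (adjusted p = 0.101), without healthy 2 (0.0538), without HCC 3 (0.0803) and with the replicate number as a block (0.0687) in limma's camera. Hepatocyte markers were higher in the same group but in another order, with 120, 420 and 1053 CPM in HCC 1, 2 and 3.

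Ribosomal protein genes were slightly lower in HCC libraries as a list. Of 90 tested members 66 had lower fitted levels, with a median log2 fold change of -0.21, and 14 were lower in each HCC library than in both healthy libraries. They summed to 204600 and 179600 CPM in healthy 1 and 2 and to 168700, 150800 and 163200 CPM in HCC 1, 2 and 3. Rps24 was at 29540 and 9795 CPM in healthy 1 and 2 against 10320 ± 2128 CPM in HCC libraries, and Rps18 at 3824 and 13300 CPM against 11730 ± 2562 CPM, so healthy 1 was the extreme library for both. The list fell in camera with a preset correlation (adjusted p = 0.0307) and had adjusted p = 0.646 with an estimated correlation, and 0 members passed adjusted over the list alone or over all genes. In camera with the preset correlation the call was lost with library totals only (adjusted p = 0.195), with no filter on low counts (0.257), with the replicate number as a block (0.0687), and without healthy 1 (0.0676), healthy 2 (0.270), HCC 1 (0.0573) or HCC 2 (0.194), and it was at 0.00274 with protein-coding genes only.

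**Figure D2:**
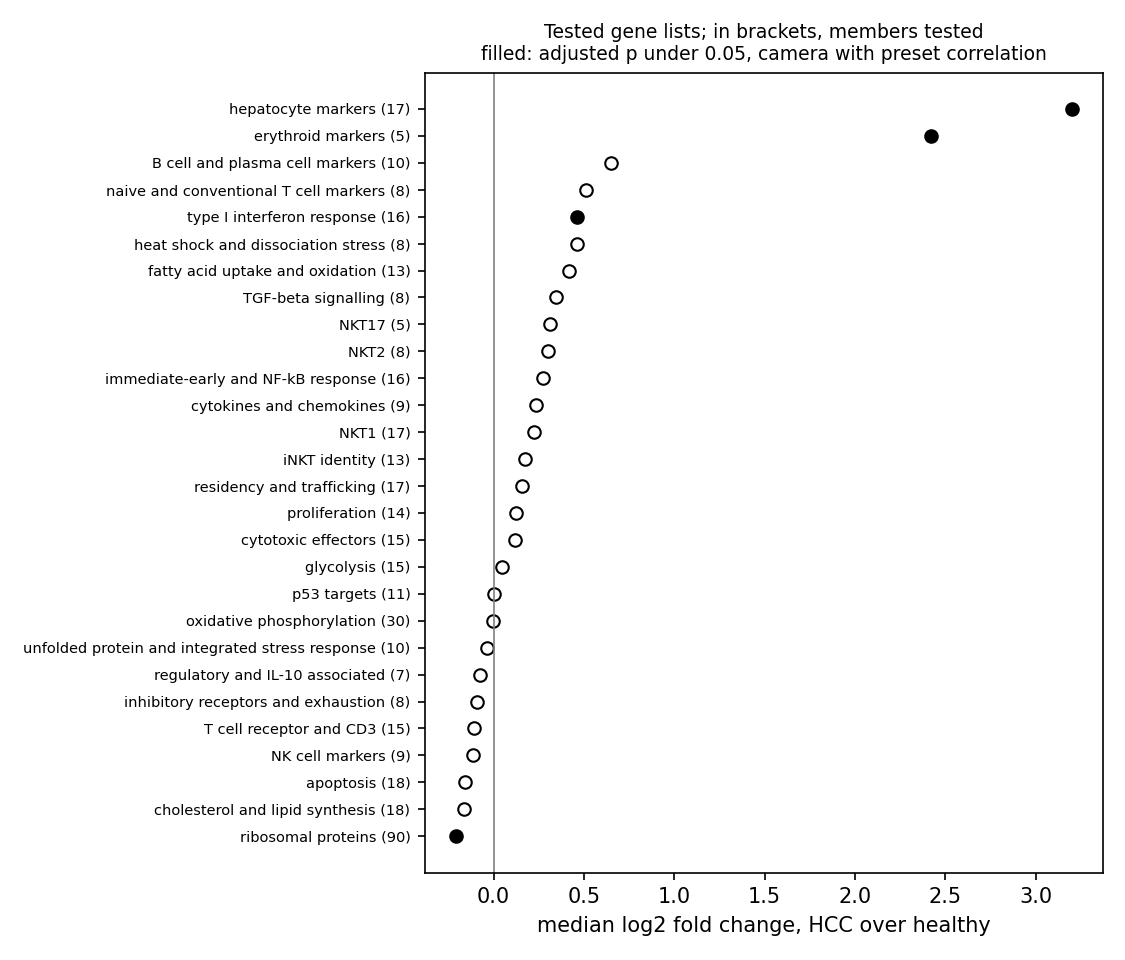
Median log2 fold change, HCC over healthy, of the 28 tested gene lists; each point is a list, numbers in brackets are the members tested, and filled points passed camera with a preset correlation. Hepatocyte (3.20) and erythroid (2.42) markers lie far from the other lists, which run from -0.21 for ribosomal proteins to 0.65 for B cell and plasma cell markers.

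Genes of T cell and iNKT identity showed no difference between the groups that passed, in data where small changes in single genes were rarely detectable. The 15 members of the T cell receptor and CD3 list summed to 5279 ± 97.2 CPM in healthy and 5160 ± 666 CPM in HCC libraries. Trac and Trbc2, the constant regions of the T cell receptor chains, were at 625 ± 42.7 and 638 ± 162 CPM and at 1873 ± 372 and 2068 ± 401 CPM. Cd3e, a signalling chain of the receptor complex, was at 234 ± 8.44 and 208 ± 68.2 CPM. The transcription factor Tbx21 (T-bet) was at 389 ± 86.7 and 304 ± 67.5 CPM, Il2rb, the receptor chain shared by IL-2 and IL-15, at 874 ± 118 and 985 ± 114 CPM, and Id2 at 1578 ± 735 and 1843 ± 163 CPM. Zbtb16, which encodes PLZF, the defining factor of iNKT development, was near or under the limit set by a count of 0 in all 5 libraries, at 0 to 1.64 CPM, and was not tested. Neither the receptor list (median log2 fold change -0.11, mean 0.013, camera adjusted p = 0.905, direction down) nor the iNKT identity list (13 tested, median 0.17, adjusted p = 0.947) passed. Both had 0 members past the threshold adjusted over the list alone and over all genes.

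Lists of the functional iNKT subsets did not pass camera with a preset correlation, and 0 of their members passed adjusted over the list alone or over all genes. Of 17 tested NKT1 genes, the subset that makes interferon gamma, 12 had higher fitted levels in HCC libraries (median log2 fold change 0.22, adjusted p = 0.253). Ccl5, a chemokine that attracts T cells, was at 1079 ± 217 and 1024 ± 123 CPM. The NKT2 list, of the IL-4-producing subset, had 7 of 8 tested members fitted higher (median 0.30, adjusted p = 0.315), with Il4ra at 118 ± 18.8 and 152 ± 13.2 CPM and Icos at 57.1 ± 29.7 and 62.5 ± 11.4 CPM. The NKT17 list had 4 of 5 fitted higher (median 0.31, adjusted p = 0.947), with Il7r at 127 ± 24.6 and 140 ± 39.8 CPM and Tmem176a at 85.7 ± 8.18 and 117 ± 83.2 CPM. In the list of regulatory and IL-10 associated genes 3 of 7 were fitted higher (median -0.075, mean 0.16, direction up, adjusted p = 0.947), with Lgals1 at 390 ± 47.3 and 370 ± 89.4 CPM and Tnfrsf18 (GITR) at 247 ± 56.1 and 224 ± 9.34 CPM.

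Effector and inhibitory gene lists did not pass camera with a preset correlation, again with 0 members past the threshold adjusted over the list alone and over all genes. Cytotoxic effectors summed to 2052 ± 71.6 CPM in healthy and 2083 ± 218 CPM in HCC libraries (15 tested, median log2 fold change 0.12, adjusted p = 0.889), with Nkg7, a cytotoxic granule protein, at 802 ± 119 and 863 ± 149 CPM and Ctsw at 435 ± 189 and 369 ± 27.1 CPM. Inhibitory receptors and exhaustion genes summed to 336.5 ± 15.0 and 289 ± 16.2 CPM (8 tested, median -0.094, adjusted p = 0.68). Of these, Cd160 was at 120 ± 30.3 and 72.7 ± 12.7 CPM, lower in all 3 HCC libraries, and Vsir (VISTA) at 114 ± 26.3 and 112 ± 0.648 CPM. Cytokines and chemokines had a median of 0.24 (9 tested, adjusted p = 0.765). Xcl1, a chemokine that attracts cross-presenting dendritic cells, was at 97.3 ± 8.37 and 168.5 ± 10.7 CPM (log2 fold change 0.79, SE 0.35), higher in all 3 HCC libraries, without passing.

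Stress and activation lists did not pass either, and none had a member past the threshold adjusted over the list alone or over all genes. All 8 tested members of the heat shock and dissociation stress list had higher fitted levels in HCC libraries (median log2 fold change 0.46, camera adjusted p = 0.0582, and 0.899 with an estimated correlation). The chaperone Hspa8 was at 442 ± 114 and 589 ± 179 CPM and Hsp90ab1 at 270 ± 2.12 and 294 ± 43.6 CPM. In camera with the preset correlation this list passed with library totals only (adjusted p = 0.0364), with HCC 2 and 3 summed (0.0143), with the replicate number as a block (0.0351) and without HCC 3 (0.00538), while it was at 0.654 without HCC 1, which held the highest Hspa8 level (794 CPM). Immediate-early and NF-kB response genes had a median of 0.27 (16 tested, adjusted p = 0.208), with Dusp2 at 254 ± 142 and 249 ± 116 CPM and Jund at 185 ± 44.3 and 157 ± 35.7 CPM. The unfolded protein and integrated stress response list had a median of -0.036 and a mean of 0.076 (10 tested, direction up, adjusted p = 0.947), with the endoplasmic reticulum chaperones Hspa5 at 504 ± 18.6 and 573 ± 90.7 CPM and Calr at 274 ± 91.3 and 283 ± 65.1 CPM. Proliferation genes had a median of 0.12 (14 tested, adjusted p = 0.889), with Tubb5 at 279 ± 31.7 and 319 ± 47.7 CPM and the replicative helicase subunit Mcm6 at 78.8 ± 20.9 and 86.1 ± 21.5 CPM.

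Metabolic lists showed no difference that passed camera, and 0 members passed adjusted over the list alone or over all genes. Glycolysis genes summed to 1555 ± 120 and 1534 ± 77.0 CPM (15 tested, median log2 fold change 0.045, adjusted p = 0.948), with Ldha, which converts pyruvate to lactate, at 355 ± 47.1 and 340 ± 90.6 CPM and the Aldoa row (ENSMUSG00000030695) at 317 ± 7.07 and 338 ± 17.5 CPM. Oxidative phosphorylation genes had a median of -0.0033 (30 tested, 16 fitted lower, adjusted p = 0.889). Among them the ATP synthase subunit Atp5e was at 874 ± 279 and 489 ± 78.2 CPM, lower in all 3 HCC libraries, and Uqcrh, of complex III, at 882 ± 317 and 761 ± 212 CPM. Fatty acid uptake and oxidation genes had a median of 0.42 (13 tested, adjusted p = 0.807), with Hadh at 51.7 ± 34.4 and 69.2 ± 16.2 CPM and Etfb at 64.4 ± 30.5 and 27.8 ± 9.78 CPM. Of 18 tested genes of cholesterol and lipid synthesis 10 were fitted lower (median -0.16, adjusted p = 0.68), and Cyp51, which like Msmo1 acts after lanosterol, was at 53.7 ± 20.8 and 33.1 ± 6.85 CPM.

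Residency, TGF-beta, apoptosis and p53 lists did not pass camera, and 0 of their members passed adjusted over the list alone or over all genes. Residency and trafficking genes had a median log2 fold change of 0.16 (17 tested, adjusted p = 0.68). Cxcr6, a chemokine receptor of liver-resident lymphocytes, was at 301 and 924 CPM in healthy 1 and 2 and at 476 ± 46.4 CPM in HCC libraries, and the integrin chain Itgal (LFA-1) at 290 ± 54.6 and 418 ± 77.8 CPM, higher in all 3 HCC libraries. TGF-beta signalling genes had a median of 0.34 (8 tested, adjusted p = 0.68), with Smad3, a signal transducer of the pathway, at 24.5 ± 19.9 and 64.8 ± 20.4 CPM (log2 fold change 1.40, and 0.74 without healthy 1) and Smad4 at 21.6 ± 5.77 and 28.8 ± 17.8 CPM. Of 18 tested apoptosis genes 13 were fitted lower (median -0.16, adjusted p = 0.68), with the survival factor Bcl2 at 144 ± 71.6 and 104.5 ± 41.4 CPM and Bcl2a1b at 161 ± 93.8 and 156 ± 30.4 CPM. p53 targets had a median of 0.0014 (11 tested, adjusted p = 0.68), with Mdm2 at 33.6 ± 5.90 and 46.3 ± 4.03 CPM and Trp53inp1 at 37.7 ± 16.3 and 37.8 ± 7.43 CPM.

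Markers of other lymphocytes were measured in all libraries at low to moderate levels, with 0 members past the threshold adjusted over the list alone or over all genes. B cell and plasma cell markers summed to 158 ± 74.7 and 239 ± 82.1 CPM (10 tested, median log2 fold change 0.65, camera adjusted p = 0.208), with Ighm at 49.9 ± 17.2 and 88.8 ± 10.6 CPM and Igkc at 0 and 41.7 CPM in healthy 1 and 2 and 31.8 ± 19.5 CPM in HCC libraries. Without HCC 1 the B cell list passed in camera with the preset correlation (adjusted p = 0.00853), while with all libraries it had adjusted p = 0.899 with an estimated correlation. Its direction turned down without healthy 1 (camera adjusted p = 0.692). Naive and conventional T cell markers had a median of 0.51 (8 tested, adjusted p = 0.253), with the chromatin organiser Satb1 at 94.8 ± 27.2 and 113 ± 15.6 CPM. NK cell markers had a median of -0.11 and a mean of 0.0028 (9 tested, direction down, adjusted p = 0.889), with Klra9 at 87.6 ± 86.0 and 108 ± 119 CPM and the kinase Txk at 59.8 ± 39.6 and 78.0 ± 28.6 CPM.

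The lists of macrophage and Kupffer cell, neutrophil, dendritic cell, liver endothelial, and stellate cell and fibroblast markers had fewer than 5 tested members and were not tested as lists. Each had 0 members past the threshold adjusted over the list alone and over all genes. Macrophage markers summed to 40.1 ± 34.7 and 30.3 ± 8.80 CPM, with Lyz2, lysozyme of myeloid cells, at 0 and 7.49 CPM in healthy and 5.82, 30.4 and 5.36 CPM in HCC libraries (log2 fold change 1.87, 0.57 without HCC 2 and 0.87 without healthy 1). Neutrophil markers consisted almost wholly of Mmp9, at 505 ± 194 and 442 ± 146 CPM. Dendritic cell markers were led by Cst3, at 122 ± 3.52 and 97.3 ± 21.3 CPM, with Bst2 at 18.2 ± 6.80 and 19.4 ± 2.19 CPM. Ptprb, of endothelium, was at 44.9 CPM in healthy 1 and 7.35 to 13.2 CPM in the other libraries. Of the collagen genes, Col1a1 was at 3.56 ± 5.03 and 5.10 ± 3.85 CPM, and Col1a2 had 0 counts in both healthy libraries and was at 0, 9.97 and 7.51 CPM in HCC 1, 2 and 3, a group mean at least 3.59-fold higher when each healthy library is set at 3 counts. The mitochondrially encoded genes had 0 rows and were not analysed here.

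Klrb1c, which encodes the NK1.1 antigen, differed far more between libraries than between groups. It was at 465 and 5.35 CPM in healthy 1 and 2, and at 452, 18.9 and 337 CPM in HCC 1, 2 and 3 (log2 fold change 0.19, SE 1.34), and did not pass in edgeR. Its neighbours on chromosome 6 (complex from 128705836 to 130386874) were looked at after this was seen. Klra9, which encodes a Ly49 receptor, was at 148 and 26.8 CPM in the healthy libraries and at 244.5, 23.6 and 56.9 CPM in the HCC libraries, while Klrc1 (NKG2A) was at 684 and 454 CPM and at 972, 680 and 561 CPM. Of the 3' words of Klra9 70.2%, and of Klrc1 77.5%, occur in other genes, against 16.5% for Klrb1c.

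**Figure D3:**
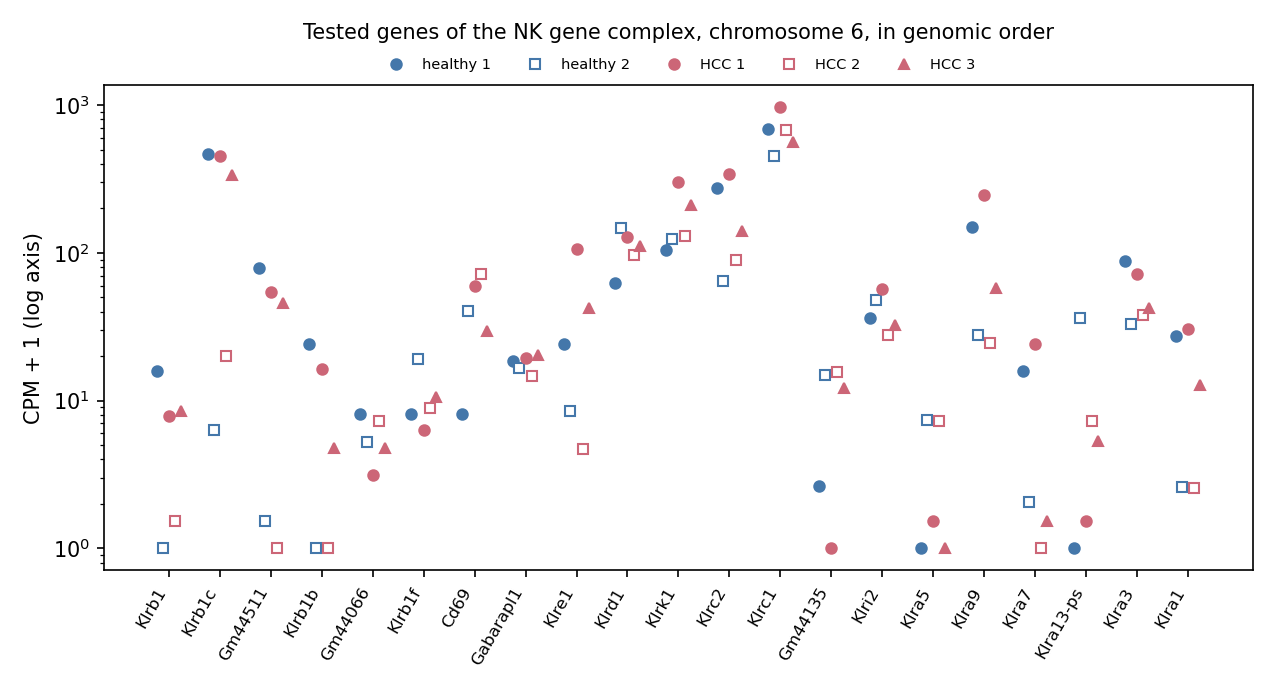
Level of the 21 tested genes of the NK gene complex in each library, in genomic order, as CPM + 1 on a log axis; points are libraries. Klrb1c is at 5.35 and 18.9 CPM in healthy 2 and HCC 2 and at 337 to 465 CPM in the other 3 libraries, while Klrc1 and Klrd1 differ far less between libraries.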

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

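The library totals only setting for lists, the protein-coding setting and the quality weights were chosen after the data had been seen, and all other alternatives were planned. The counts of 0 higher and 0 lower genes in edgeR (307 at an unadjusted p under 0.05) held with DESeq2 size factors (312), library totals only (267), 10 CPM in 2 libraries (237), HCC 2 and 3 summed (133), markers of other cell types removed (293) and protein-coding genes only (274), and with limma-voom without (208) and with quality weights (117). With no filter on low counts 29 genes were higher and 24 lower, and 21 of the 24 had their highest level in healthy 1. Of the 29, 19 were Mup or hepatocyte list genes, 5 erythroid list genes and 5 of neither kind. Among the last was Zfp276, with 628 counts over all libraries and the smallest adjusted p in that setting (5.96e-13 in edgeR). The replicate block, which takes libraries with the same number as paired, gave 3 higher (Hbb-bs, Hbb-bt and Mup14) and 0 lower, and the DESeq2 Wald test gave 9 higher and 0 lower. Leaving out 1 library gave 0 to 102 higher and 0 to 94 lower genes, and only the fit without healthy 2, in which 1 healthy library is assumed to vary like the HCC libraries, gave any. The cause of these differences was not tested. Of the lists, the 3 higher became 0 in camera with an estimated correlation and 0 in fry, and the 1 lower became 0 with library totals only, with no filter, with the replicate block, with an estimated correlation and in fry. Leaving out 1 library gave 0 to 1 lower lists. In camera with the preset correlation the hepatocyte and erythroid lists passed under each alternative run for lists (10 CPM in 2 libraries and markers removed were run for genes only), with adjusted p from 4.21e-33 to 0.000561 and from 3.34e-17 to 0.000163. The interferon list ran from 0.000259 to 0.101, the value with the replicate block being 0.0687, and the ribosomal list ran from 0.00274 to 0.270, with 0.0687 in the block. Heat shock ran from 0.00538 to 0.654 and passed with the block at 0.0351. Of 1314 values of 84 named genes under an alternative, 1237 kept their sign and 77 did not, 0 of the 77 past the threshold. None of the 77 was among the 376 values of the 24 genes chosen with all HCC libraries on 1 side of both healthy libraries. That choice largely fixes their sign, so this is no evidence of stability. Under an alternative 26 values passed the threshold, some of them in the fit without healthy 2, which holds 1 healthy library. In that fit the log2 fold change of Smad3 was 2.68 (0.74 without healthy 1) and that of Rps24 was -1.46. With library totals only the log2 fold change was 0.13 for Ccl5, 0.11 for Lgals1, 0.059 for Tnfrsf18, 0.18 for Vsir, 0.095 for Dusp2, 0.11 for Ldha, 0.069 for Bcl2a1b and 0.017 for Mmp9, all negative with TMM, in a setting that raised the median of all genes from 0.0047 to 0.16. With the replicate block it was -0.19 for Trac, 0.035 for Ccl5, -0.31 for Tmem176a, 0.38 for Dusp2 and 0.21 for Bcl2a1b. With HCC 2 and 3 summed it was 0.025 for Lgals1, 0.13 for Dusp2, 0.027 for Bcl2a1b and -0.019 for Trp53inp1. Values near 0 also changed sign for Vsir (0.040 with no filter, 0.0094 in DESeq2, 0.0011 in limma-voom), Dusp2 (0.0070 with no filter, 0.035 with quality weights), Bcl2a1b (0.069 in limma-voom, 0.096 with quality weights), Trp53inp1 (-0.0012 with DESeq2 size factors, -0.0054 with 10 CPM in 2 libraries, -0.075 with protein-coding genes) and Calr (-0.023 with protein-coding genes). Leaving out 1 library at a time, the lowest and highest log2 fold changes of the genes that changed sign were Trbc2 -0.053 to 0.41, Trac -0.17 to 0.19, Id2 -0.19 to 0.85, Ccl5 -0.21 to 0.14, Icos -0.33 to 0.84, Il7r -0.037 to 0.36, Tmem176a -0.31 to 0.73, Lgals1 -0.29 to 0.050, Tnfrsf18 -0.30 to 0.10, Nkg7 -0.042 to 0.32, Ctsw -0.57 to 0.29, Vsir -0.18 to 0.23, Dusp2 -0.51 to 0.76, Jund -0.41 to 0.022, Calr -0.21 to 0.43, Mcm6 -0.13 to 0.48, Ldha -0.18 to 0.15, Uqcrh -0.48 to 0.20, Hadh -0.14 to 1.39, Cxcr6 -0.96 to 0.71, Smad4 -0.22 to 0.77, Bcl2a1b -0.55 to 0.77, Bcl2 -0.85 to 0.15, Trp53inp1 -0.33 to 0.52, Satb1 -0.027 to 0.63, Klra9 -1.11 to 2.02, Txk -0.18 to 1.34, Igkc -0.40 to 8.91, Mmp9 -0.49 to 0.25, Bst2 -0.19 to 0.53, Ptprb -2.02 to 0.22, Col1a1 -0.43 to 6.28, Rps24 -1.46 to 0.069, Rps18 -0.19 to 1.67 and Klrb1c -0.73 to 5.64. The highest values of Igkc and Col1a1 are fitted against a lone healthy library with 0 counts and are no estimate of a fold. Depth limits genes with few counts, since 3 counts are 1.58 to 1.64 CPM.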

Other observations

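The tests of scaling, of healthy 1 and of the NK gene complex, and the mitochondrial values, were chosen after the results they concern had been seen, whereas the second hepatocyte and red cell lists and their bounds were written before their values were seen. The reading that a bound must be cleared by more than 1 SE was applied to both lists after their values were seen.

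Rows annotated as pseudogenes that share most of their sequence with mitochondrial genes were higher in HCC libraries as a sum. They held 11030 and 14050 CPM in healthy 1 and 2 and 21470, 18830 and 23700 CPM in HCC 1, 2 and 3, a ratio of 1.7 between group means. Gm28437, which resembles the cytochrome oxidase gene mt-Co3, was at 7471 ± 332 CPM in healthy and 11760 ± 2962 CPM in HCC libraries (n = 2 and 3). Gm10925, which resembles mt-Atp6, was at 1595 ± 909 and 4568 ± 973 CPM (log2 fold change 1.52). Gm28439, which resembles mt-Nd4, was at 455 CPM in HCC 1 and 11.5 to 43.4 CPM in the other libraries. Gm28437 was the largest part of the sum, and Gm28438, which resembles mt-Nd3, was at 947 ± 413 and 889.5 ± 147 CPM. None of these rows passed in edgeR with the filter on low counts, and Gm28439 passed without it (log2 fold change 3.15, adjusted p = 2.25e-06).

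Hepatocyte and red cell transcripts were higher in the HCC libraries, in cells sorted for tetramer and T cell receptor after red cell lysis, with Alb at 6.88 to 201 CPM and Hba-a2 at 2838 to 6720 CPM. Scaling is argued against, since the TMM factors ran only from 0.8299 to 1.12, too close to each other to give such folds. With library totals only the tested members of both lists had a median log2 fold change of 3.05, a result these factors could hardly have changed. Both settings divide by the totals, which ran from 1718452 to 2224356, so depth was not tested separately. RNA or cells of hepatocytes may be the source. A second list of 48 hepatocyte genes that shares no member with the first had a ratio of 2.37 (SE 1.64) between HCC and healthy. Of its 8 tested members 7 were fitted higher, with a median log2 fold change of 1.2. Its levels were 88.1 and 40.1 CPM in healthy against 31.2, 101 and 324 CPM in HCC libraries, a spread that leaves this open. For RNA or cells of the red lineage a second list of 16 genes had a ratio of 1.11 (SE 0.197). This was under the 1.2 set in advance to speak against it but within 1 SE of that bound. Tmem14c, at 126 CPM in both groups, made up most of the list's level and would hide a small share. Of the list's 4 tested members 3 were fitted higher, with a median log2 fold change of 0.686, so this stays open too. A change of these transcripts within iNKT cells or in liver tissue of tumour-bearing mice was not tested.

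Healthy 1 stood apart in 40 genes, named here after their values were seen, with 11 more than 8-fold above and 29 more than 8-fold below every other library (with 1.6 CPM added to each level), against 0 or 1 gene for each other library. Low sequencing depth is argued against for its few detected genes, since healthy 1 had the largest total (2224356) and the fewest genes with a count (10861). After thinning to 1718452 counts it kept 10839 genes and the others 11822 to 13140. Thinning could only lower its number, so it adds no separate test. Few distinct molecules in that library could account for the 29 genes below, such as H2-T23 at 1.64 CPM against 38.6 to 59.3 CPM and Malat1 at 0 against 13.4 to 103 CPM. For the 11 genes above, few distinct molecules and a source shared by the libraries stay open. Kif3a, for example, was at 1612 CPM against 24.6 in healthy 2 and 187, 128 and 87.4 in HCC 1, 2 and 3. All 11 had HCC 1 and then HCC 2 as their highest other libraries. The whole order was the same in 9, of which 1 gene had every step beyond 2 counting SD. Reads assigned to the wrong library could also give such an order. The level in HCC 1 was 6.85 to 11.6% of that in healthy 1. The 8-fold rule that chose these genes caps this share from above but sets no lower end. The rule alone therefore does not give its narrow range, which leaves such reads open. Another cell type or a mislabelled sample stays open too. A T cell receptor and CD3 level at 100% of the median of the others cannot show a minor addition. Healthy 1 had the highest summed liver endothelial (54.2 against 8.92 to 24.1 CPM) and macrophage markers (64.6 against 15.5 to 37.0 CPM). Ptprb alone, however, held 44.9 of the 54.2 CPM, and Lyz2 was at 0 CPM in healthy 1. Marco, another macrophage marker, had 50 counts over all libraries, with 0 in 3 of them. It passed as lower in HCC libraries only with no filter on low counts (adjusted p = 0.0126 in edgeR). These sums thus neither show nor exclude a cell type. No biological explanation was tested.

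Receptor genes of the NK gene complex differed between libraries within both groups, and Klrb1c, Klrb1b and the overlapping Gm44511 were low in healthy 2 and HCC 2 alike. A share of NKT1 cells that varied as widely as Klrb1c (465 against 5.35 CPM) is argued against. The 13 NKT1 genes outside the complex had a median ratio of 2.19 between highest and lowest library. Their ratios ran from 1.39 for Ccl5 to 8.31 for Il18r1 and 8.51 for Il12rb2. A smaller change in this share stays open, since the ratio ignores the order of the libraries. Genes that are also expressed outside NKT1 cells would moreover vary less than the share. Variation tied to the locus stays open. The complex holds 5 of the 85 genes that vary most within groups (Klrb1c, Gm44511, Klrb1b, Klra7 and Klra13-ps), but it was looked at because of Klrb1c. Without Klrb1c and the overlapping Gm44511, the remaining 3 were matched by 9 of 8060 other runs of 19 neighbouring tested genes, 0.112% of them. These runs overlap each other and are not independent, so this share is no p value. Klrb1b, kept among the 3, also overlaps Gm44511 on the genome. Reads shared between the receptor genes, the choice of receptors that single cells make, and a difference in strain background at this locus were not separated. Libraries of both groups showed low and high levels, so the design gives no group to which the pattern belongs.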
